A study of Homo sapiens with 6 samples.

How the data were processed

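RNA sequencing was done on 6 libraries of T47D cells, 3 of RNA captured with biotin-carrying miR-432-5p and 3 of RNA from untreated parental cells. Per the labels, cells were transfected with a lipid reagent, RNA was purified with TRIzol and a column, and libraries were made with a stranded kit that selects polyadenylated RNA. Control RNA did not pass through a mock capture, so capture, transfection and bait cannot be separated. The aligner, the counting tool and the annotation are not given in the sources used here. The submitters' processing notes name DESeq2 and hg19 with no version or role.

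The FPKM values, fragments per kilobase and per depth, were deposited by the authors for each library, and the tool that made them is not given. Per the file headers, the same table holds group means, which the authors set to 1 where they were lower, and a fold change, the ratio of those means, with its log2. The authors' deposited table of DESeq2 results holds a mean normalised count per gene (a signal over libraries, not per library), a log2 fold change with its standard error, a Wald statistic (a score equal to the fold change over its error), and a p-value with its adjusted form, per the file headers. Its fold change is control over captured and was turned here to captured over control. Of its 21876 genes, 2520 have no adjusted p, and 634 with a mean count above 0 have a log2 fold change of exactly 0 and a p of 1, so the mean count is not read here as the mean of these 6 libraries alone. In 26 names a spreadsheet had turned the symbol into a date-like form.

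The FPKM table had 7039 rows with values. Removing 1 without a name, 1 repeat (SMAD3) and 2 with stand-in captured values (TGFBR1 and TGFBR2, at 1 in each captured library) left 7035 genes. A leading block of 15 genes was chosen by the depositors, and all other rows have a captured mean above the control mean, with means under 1 set to 1. No direction can therefore be read from how many genes are higher, and the totals below are of the listed genes, not of whole libraries. FPKM of listed genes summed to 8061, 7882 and 7606 in control and to 439253, 464260 and 254264 in captured libraries. The 10 highest genes held 14.3% to 15.3% of that sum in control libraries and 40.6%, 47.3% and 58.2% in captured libraries 1 to 3. The most frequent ratio between a pair of libraries, across genes above 0 in both, was taken as their relative depth. Each gene at that ratio was taken to hold 1 fragment, which with its transcript length gave a number of fragments. Genes at that ratio with more fragments would make this number too low.

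Since the table gives FPKM and no counts, limma 3.58.1 (eBayes with trend, R 4.3.3) was used on log2(FPKM + 1), two-sided, with Benjamini-Hochberg adjustment over the 5062 genes that had an FPKM of at least 1 in at least 3 samples. Fold changes from it are on the log2(FPKM + 1) scale, which understates those of low genes. A gene is called higher or lower at an adjusted p under 0.05. An exact 0 is reported as listed at 0, with no fold against it. Gene lists were tested with camera (preset correlation of 0.01, and again with an estimated correlation), fry and 10000 random lists matched on expression, with adjustment over the lists of at least 5 tested members. This gave 5 of 21 lists in the FPKM table. On the Wald statistics of the authors' deposited table, cameraPR tested 19 lists, a step added after the data were seen. There the random lists were matched on that table's mean count and not on the level in control RNA. The 21 lists, the tests and the rule for named genes were fixed before the data were examined. They cover TGF-β signalling, its response genes, BMP and activin signalling, the CDK4/6 module, proliferation, oestrogen receptor and luminal genes, microRNA machinery, interferon, stress, cholesterol and lipid synthesis, ribosomal proteins, nuclear and mitochondrial respiratory chain genes, long noncoding RNAs, short structured RNAs, histones, KRAB zinc fingers, and markers of fibroblasts, leukocytes, basal epithelium, and erythroid and liver cells. FN1 and CDKN2B are among the members that more than 1 list holds.

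Named genes were the 10 with the largest positive and the 10 with the largest negative log2 fold change among called genes with no overlap between groups and a mean FPKM of at least 5, the 2 members of each list with the smallest adjusted p (4 for the TGF-β and CDK4/6 lists), and TGFBR3, TGFBR2, SMAD4, CDK6, CDK4, RB1 and CCND1. The rule was applied to the FPKM table and, for list members, also to the authors' deposited table. Exceptions named after their values were seen are the other genes of the leading block, the genes with the smallest p in the authors' deposited table, GAPDH and ACTB, members of the gene families, and spike-in sequences. Some genes that the rule takes are not reported here and were not replaced. Genes of families with near-identical copies, such as ribosomal proteins, histones, olfactory receptors and zinc fingers, are uncertain, since how shared reads were counted is not given. The same holds for overlapping and antisense genes, because the sources do not say that counting used strand.

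Seed sites were searched in the 3' UTR of each gene's longest coding transcript in GENCODE release 29 on GRCh38, and all coordinates are of that build, which differs from the hg19 named by the submitters. Symbols, older ones included, matched that annotation for 19655 of 21876 genes (89.85%) of the authors' deposited table and 6053 of 7035 (86.04%) of the FPKM table. The difference in median log2 fold change between genes with and without the site was ranked among the 420 sequences of 7 bases with the same composition, and a linear model added transcript length, 3' UTR length, GC content and mean expression (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6, figures with matplotlib 3.10.9).

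The steps were tested on simulated data for the captured and control comparison. In 5062 simulated genes with 200 changed, limma recovered 8% of those with a log2 change of 1.5, 26% at 2, 72% at 3 and 98% at 4, with 5 false calls, so simulated changes under a log2 size of 3 were often missed. Both simulated groups took their means and spread from the captured libraries. In the real data, 3244 of the 5062 tested genes were at 0 in every control library. These shares therefore do not give the sensitivity of the real comparison. A test of recovery at sizes 1.5 and 3 alone first fell short of a set share of 80%, which led to the larger sizes. Camera gave a planted list of 20 genes an adjusted p of 7.81e-13 and an unchanged one 0.67. With a shift of 1 planted in genes with a site, among 2918 genes, the seed step returned a coefficient of 0.786 and rank 7 of 420, with -0.214 when nothing was planted.

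Alternatives were quantile normalization, equal totals, limma without trend, no filter, an FPKM of at least 5, a pseudocount of 0.1, a minimum 2-fold change, the replicate number as a block, leaving out each library and the authors' deposited table. Others were added after the data were seen, namely leaving out the leading block and using genes of both tables.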

Results

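RNA sequencing was used to look for transcripts bound by the microRNA miR-432-5p in T47D cells, an established human breast cancer line of luminal, oestrogen receptor-positive type. A synthetic copy of the microRNA that carried biotin served as bait after transfection, and the RNA recovered with it made 3 captured libraries. The 3 control libraries were made from RNA of untreated parental cells. The comparison was therefore between captured RNA and whole-cell RNA, and no mock capture was among the samples. The mature microRNA, TCTTGGAGTAGGTCATTGGGTGG written as DNA, lies on the plus strand of chromosome 14 at 100884496 to 100884518 (GRCh38), within the MIR432 hairpin gene at 100884483 to 100884576. Its seed, bases 2 to 8, pairs with the 7-base site CTCCAAG.

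The deposited FPKM table held 7039 rows with values, and the authors' deposited table of fold changes held 21876 genes. FPKM summed over the table came to 8061, 7882 and 7606 in control libraries 1 to 3 and to 439253, 464260 and 254264 in captured libraries 1 to 3. Of the listed genes, 73.8%, 76.2% and 75.5% were at 0 in the control libraries and 1.14%, 0.909% and 8.98% in the captured libraries. Apart from a leading block of 15 genes chosen by the depositors, rows were kept only where the captured mean exceeded the control mean, each set to at least 1, so the number of genes in each direction in that table was set by its selection. The most frequent ratios of FPKM values placed the depth of control libraries 2 and 3 at 0.80 and 0.88 times that of control library 1. The median estimate for control library 1 was 947000 fragments (quartiles 551000 and 1582000), an uncertain value that takes each gene at that ratio as 1 fragment. The corresponding ratios placed captured libraries 2 and 3 at 1.12 and 2.45 times the depth of captured library 1. There the FPKM of genes at the ratio did not follow transcript length (Spearman -0.007 across 182 genes, against -0.44 across 27 genes in control libraries), so these ratios are uncertain. The labels do not say whether replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical. Among genes listed at 0 in control libraries, captured FPKM was almost unrelated to the other table's mean count over samples (Spearman 0.05 across 2806 genes), whereas control FPKM rose with that count among genes of the control side (0.79 across 659 genes). The directions below are therefore given with the table each comes from.

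The series concerns repression of the TGF-β pathway by microRNAs and resistance to CDK4/6 inhibitors, and the genes of both pathways were examined first. In the authors' deposited table, 20 of 27 TGF-β signalling components were lower in captured RNA, 3 were higher and 4 did not pass the adjusted threshold. Adjusted over the list alone, the numbers were also 20 lower and 3 higher. SMAD4, the common partner of receptor-activated SMAD proteins, had a log2 fold change (captured over control) of -5.09 ± 1.26 (SE) and a DESeq2 adjusted p of 0.000144 in the authors' deposited table. TGFBR2, the type II receptor, was lower by a log2 fold change of -6.92 ± 1.96, and SMAD7, an inhibitory SMAD, by -6.19 ± 1.99. TRIM33 and STRAP, regulators of SMAD signalling, had values of -7.17 ± 0.935 and -6.36 ± 0.939. The 3 components higher in the authors' deposited table were the ubiquitin ligase SMURF2 (1.84 ± 0.222), the type I receptor TGFBR1 (1.87 ± 0.339) and the ligand TGFB2 (5.51 ± 1.25). TGFBR3, the co-receptor betaglycan, had a log2 fold change of -1.19 ± 1.82 and an adjusted p of 0.535 there.

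The FPKM table listed 10 of the 28 TGF-β signalling components, and SMAD4, SMAD7 and TGFB1 were called the other way there. TGFB1 had a log2 fold change of 1.95 by limma and of -1.25 in the authors' deposited table. TGFBR3, TGFB3, SMAD3 and ENG also differed in sign, without passing in the authors' deposited table. All 8 components tested in it were higher in captured RNA by limma, and 7 of them came from the depositors' chosen block, which is not independent evidence of a direction. SMAD7 was at 4.90 ± 0.832 FPKM (SD, n = 3) in control and 112 ± 40.0 in captured libraries, a log2 fold change of 4.20 ± 0.437 (SE) on the log2(FPKM + 1) scale with a limma adjusted p of 6.08e-06. SMAD4 was at 3.00 ± 0.353 and 17.9 ± 4.19 FPKM (limma adjusted p of 0.000323). TGFBR3 was at 0.295 ± 0.260 and 2.04 ± 0.426 FPKM (limma adjusted p of 0.000527). TGFB2 was higher in both tables, with control libraries at 0, 0 and 0.297 FPKM and captured libraries at 41.0, 35.9 and 13.4 FPKM. TGFBR1 and TGFBR2 were listed at exactly 1 in each captured library, a stand-in value, and were not tested. The list's median log2 fold change of 2.31 was close to the 2.61 of all 5062 tested genes, and camera did not separate the list from other genes (adjusted p = 0.951). After quantile normalization the log2 fold changes of SMAD4 and TGFBR3 turned to -1.68 and -1.23 and that of SMAD7 fell to 0.06 (adjusted p = 0.731), so its call was lost, and after scaling to equal totals those of SMAD7, SMAD4 and TGFBR3 were -0.96, -2.74 and -1.24. Both scalings lower the listed genes as a group, by amounts that differ between genes, since the total of the selected genes was 49.2 times higher in captured than in control libraries. These values therefore place a gene among the listed genes and do not test its own direction.

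**Figure D1:**
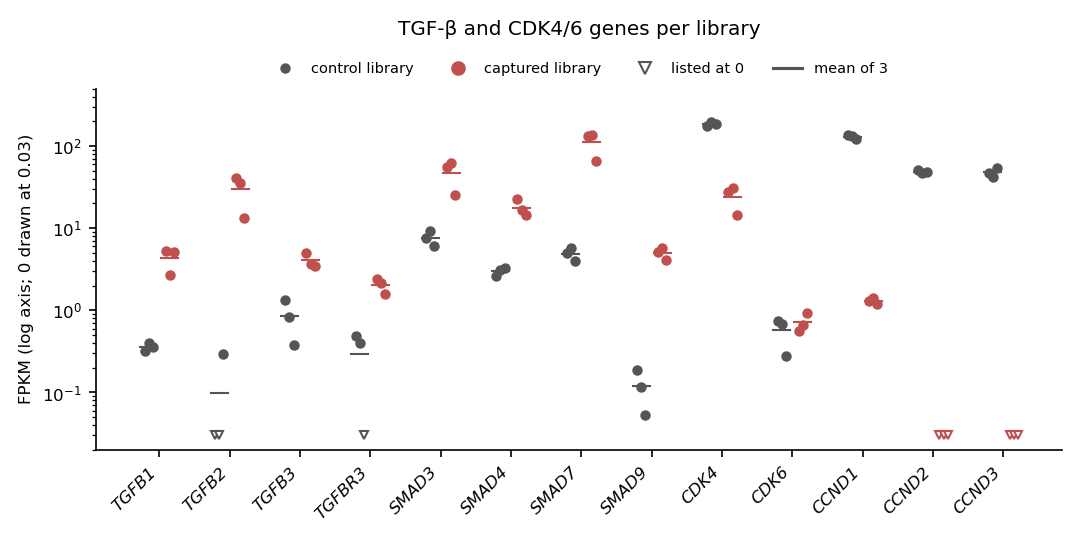
FPKM on a log axis of 13 genes from the block placed first by the depositors, with each point a library (grey, 3 control; red, 3 captured), each bar the mean of 3 and open triangles values listed at 0; TGFBR1 and TGFBR2 are left out because their captured values are stand-ins. CCND1 lies at 121 to 137 FPKM in control libraries and at a mean of 1.30 in captured libraries, while SMAD7 lies at 4.03 to 5.68 in control and at 65.8 to 136 in captured libraries.

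CCND1 and CDK4 were lower in captured RNA in both tables. Of 26 genes of the CDK4/6, cyclin D and RB module, 19 were lower in captured RNA, 4 were higher and 3 did not pass in the authors' deposited table, with the same 19 and 4 adjusted over the list alone. CCND1, which encodes cyclin D1, had a log2 fold change of -10.81 ± 1.72 and CDK4 one of -2.82 ± 0.198 in the authors' deposited table. RB1, the retinoblastoma gene, was also lower there (-6.22 ± 1.92, adjusted p of 0.00212). CDK6 had a log2 fold change of -0.67 ± 0.659 and an adjusted p of 0.328 there. CDKN2B, which encodes an inhibitor of CDK4 and CDK6, was higher in the authors' deposited table, by 6.76 ± 0.929. In the FPKM table CCND1 was at 130 ± 8.20 FPKM in control and 1.30 ± 0.109 in captured libraries, and CDK4 at 186 ± 11.3 and 24.3 ± 8.51, with limma adjusted p of 2.23e-07 and 3.48e-05. CCND2 and CCND3 were listed at 0 in each captured library and at 48.9 ± 1.89 and 48.0 ± 6.43 FPKM in control libraries. As the same block holds stand-in values for TGFBR1 and TGFBR2, these 0 values may be stand-ins too, and the calls of both genes are uncertain. For CCND3 the authors' deposited table gave a smaller log2 fold change of -1.56 ± 0.276, and CCND2 had no entry there. CDK6 stayed below the filter, at 0.749, 0.691 and 0.277 FPKM in control and 0.565, 0.656 and 0.934 in captured libraries. CCND1, CCND2, CCND3 and CDK4 were the 4 genes called lower by limma among the 5062 tested (9 without captured replicate 1, 9 without captured replicate 2 and 7 with the replicate number as a block), and all came from the depositors' chosen block, so their direction is not independent evidence. A camera test of this module in the FPKM table is not read, since 4 of its 5 tested members came from that block and the other genes were listed only if higher in captured RNA. Without that block limma called 0 of 5050 genes lower, and 0 at an unadjusted p under 0.05.

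Response genes of the TGF-β pathway were examined next. Of 19 members, 12 were lower, 4 were higher and 3 did not pass in the authors' deposited table, and cameraPR did not separate the list from other genes (adjusted p = 0.0978). ID2, a dominant-negative helix-loop-helix factor, had a log2 fold change of -5.91 ± 0.698 there, TSC22D1 one of -2.60 ± 0.287 and KLF10 one of -3.36 ± 0.448, whereas LTBP2, an extracellular matrix protein, was higher by 5.55 ± 0.656. In the FPKM table PMEPA1, a TGF-β-induced inhibitor of the pathway, was at 11.3 ± 1.03 in control and 279 ± 114 FPKM in captured libraries (limma adjusted p of 4.09e-06), against -2.80 ± 0.456 on the log2 scale in the authors' deposited table. The log2 fold change of PMEPA1 by limma was 0.04 with quantile normalization (adjusted p = 0.744) and -0.89 with equal totals (adjusted p = 0.000461). Both scalings lower the listed genes as a group. Of 17 BMP and activin components, 7 were lower, 4 higher and 6 did not pass in the authors' deposited table. BMP7, a ligand of the family, and the signal transducer SMAD5 had log2 fold changes of -2.41 ± 0.253 and -3.43 ± 0.614 there. All 5 BMP and activin components tested in the FPKM table were higher by limma, and camera did not separate them from other genes (adjusted p = 0.864). Under those scalings SMAD9 came to -0.84 with quantile normalization (adjusted p = 0.00321) and INHBB to -1.48 with equal totals (adjusted p = 0.0274). The cameraPR adjusted p of this list in the authors' deposited table was 0.504. Adjusted over the list alone, 7 were lower and 2 higher there, and the response genes again gave 12 and 4. Among matched random lists, the BMP and activin list lay at percentile 14.5 and the response genes at 5.54.

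Proliferation, luminal, ribosomal and respiratory chain transcripts were lower in captured RNA in the authors' deposited table. Across that table, 7978 genes were lower and 7330 higher among 19356 with a DESeq2 adjusted p. Of 75 cytosolic ribosomal protein genes, 67 were lower and 4 higher, with RPS14 at -2.94 ± 0.169 and RPL32 at -5.65 ± 0.335. Of 66 nuclear-encoded respiratory chain genes, 62 were lower and 1 was higher, with COX6C at -3.41 ± 0.223. All 30 proliferation genes were lower, among them CCNB1 (-5.46 ± 0.582) and BIRC5 (-2.34 ± 0.252). Of 31 oestrogen receptor and luminal genes, 26 were lower and 2 higher. The luminal transcription factor GATA3 had a log2 fold change of -4.51 ± 0.147 and the luminal keratin KRT18 one of -6.99 ± 0.282 there. Of 26 cholesterol and lipid synthesis genes, 20 were lower and 2 higher, with the desaturase SCD at -4.95 ± 0.549. For these 5 lists, for TGF-β signalling and for the CDK4/6 module, cameraPR on the Wald statistics of the authors' deposited table gave adjusted p of 2.75e-16, 7.81e-15, 2.57e-08, 1.93e-11, 0.00951, 0.0427 and 0.0471 in that order. That test takes a preset correlation and no per-library values, so no estimated correlation was available for it. Among 10000 random lists matched on this table's mean count, the median log2 fold changes of these lists lay at percentiles 0.01, 0, 0.02, 0.28, 1.64, 0.69 and 5.51. That of the CDK4/6 module was thus within the range of matched lists. The matching left the level in control RNA unmatched. Among 2806 genes at 0 in control libraries with a fold change above 0, the mean count followed the log2 fold change (Spearman 0.949). These percentiles therefore do not separate a list's direction from its abundance in control RNA. Adjusted over each list alone, the numbers of lower genes were 67, 62, 30, 26, 20, 20 and 19. As captured FPKM was almost unrelated to this table's mean count among the genes compared, it is uncertain whether its captured counts belong to the genes named, and these p-values describe the table as deposited without showing loss of these transcripts on capture.

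**Figure D2:**
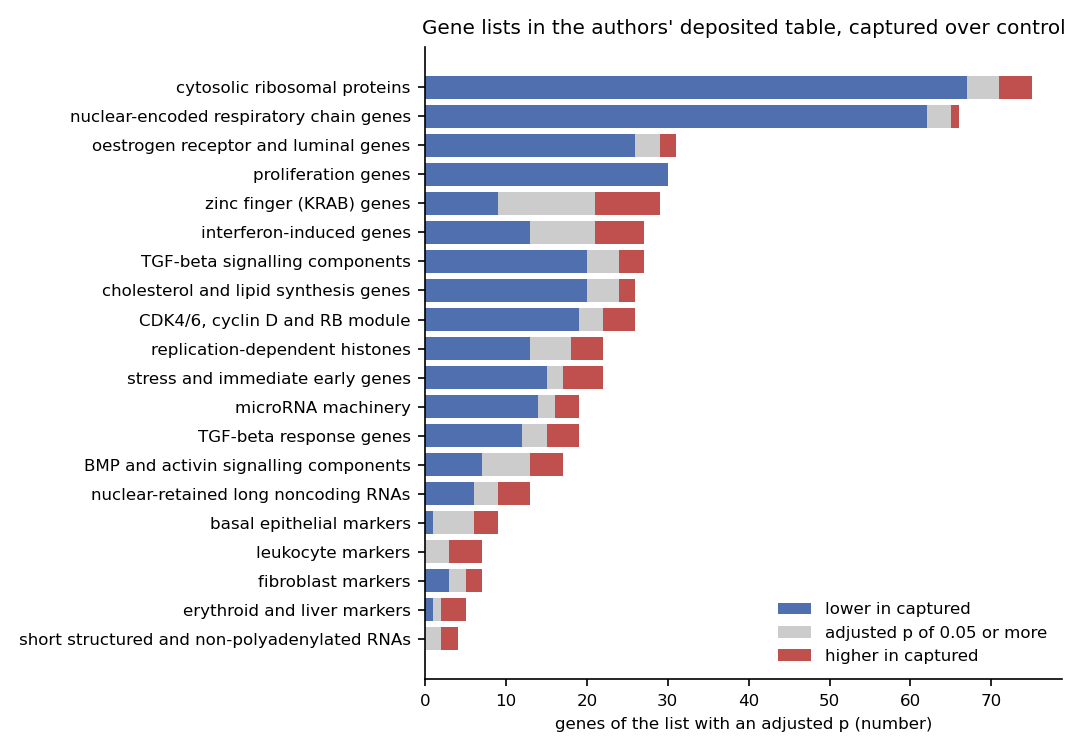
Number of genes (x axis) of each fixed list (y axis) that had an adjusted p in the authors' deposited table, split into lower in captured RNA (blue), adjusted p of 0.05 or more (grey) and higher in captured RNA (red). All 30 proliferation genes and 67 of 75 ribosomal protein genes were lower, and 4 of 7 leukocyte markers were higher.

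Most other lists went both ways in the authors' deposited table, and cameraPR separated none of the tested ones, here or among the cell type markers, from other genes (adjusted p from 0.193 to 0.904). Among matched random lists, however, the median log2 fold change of the histones lay at percentile 0.37, that of microRNA machinery at 3.39, of stress genes at 3.49, of interferon-induced genes at 11.8, of nuclear-retained RNAs at 24.5 and of KRAB zinc finger genes at 43.6. The 2 tests differ most for histones, also for the leukocyte markers given below (98.9), and less for microRNA machinery and stress genes. As the matching left the level in control RNA unmatched, these percentiles do not show a direction apart from abundance in control RNA. Adjusted over each list alone, the counts were the same except for KRAB zinc finger genes, with 8 lower and 7 higher. Of 19 microRNA machinery genes, 14 were lower and 3 higher, with the Argonaute gene AGO3 at 3.46 ± 0.381 and the helicase gene DDX6 at -3.98 ± 0.651. Interferon-induced genes divided into 13 lower and 6 higher of 27, with IFI27 at 6.05 ± 0.950 and IFITM3 at -10.96 ± 1.74. Stress and immediate early genes divided into 15 lower and 5 higher of 22, and the stress genes GADD45A and DDIT3 were at 4.12 ± 0.245 and 3.28 ± 0.213. Replication-dependent histones divided into 13 lower and 4 higher of 22. Nuclear-retained long noncoding RNAs divided into 6 lower and 4 higher of 13, with MALAT1 at -3.58 ± 0.208 and HOTAIR at 3.91 ± 0.310. KRAB zinc finger genes divided into 9 lower and 8 higher of 29. In the FPKM table, 6 of the 8 tested KRAB zinc finger genes were higher by limma but less so than other genes (camera adjusted p = 0.00469, and adjusted p = 0.424 with an estimated correlation). Of the 4 short structured RNAs, 2 were higher and 0 lower, and the vault RNA gene VTRNA1-1 was at 8.29 ± 1.94. Mitochondrially encoded genes were not analysed here, since 0 of 15 had an entry.

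Markers of other cell types were included among the lists. Of 7 leukocyte markers, 4 were higher and 0 lower in the authors' deposited table, with TYROBP at 8.11 ± 1.99. Of 5 erythroid and liver markers, 3 were higher and 1 lower, with the plasma protein gene TTR at 7.93 ± 2.01. Of 9 basal epithelial markers, 3 were higher and 1 lower, and of 7 fibroblast markers, 2 were higher and 3 lower. Among matched random lists these 4 lay at percentiles 98.9, 90.5, 48.2 and 24.0, again without matching on the level in control RNA. In the FPKM table the 5 leukocyte markers tested were all higher by limma, as were 4511 of all 5062 genes by the table's selection, and camera did not separate them from other genes (adjusted p = 0.864). Lysozyme, LYZ, reached 363 ± 196 FPKM in captured libraries with control libraries at 0.378, 0 and 0 FPKM. The authors' deposited table gave LYZ a log2 fold change of -1.03 ± 2.89 with no adjusted p.

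In the FPKM table, limma called 4511 higher and 4 lower of 5062 tested at an adjusted p under 0.05, and 547 did not pass. All 3244 tested genes that were at 0 in every control library were called higher. The filter admits such a gene only if all 3 captured values are at least 1, so this count follows from the selection and is not separate evidence. The readthrough gene PPT2-EGFL8 and the microRNA gene MIR4712 were listed at 0 in all control libraries and at means of 22779 ± 5091 and 10085 ± 7863 FPKM in captured libraries. The authors' deposited table gave PPT2-EGFL8 a log2 fold change of 4.37 ± 2.30 (adjusted p of 0.0709) and MIR4712 one of 0 with no adjusted p. RSPO4, an activator of Wnt signalling, was listed at 0 in control libraries and at 3395 ± 2667 FPKM in captured libraries. PEX2, needed for peroxisome assembly, rose from 11.4 ± 0.846 to 22260 ± 5408 FPKM (limma adjusted p of 6.65e-09), whereas the authors' deposited table gave it a log2 fold change of -7.51 ± 1.81. The numbers depended on scaling. With quantile normalization 1674 genes were higher and 1760 lower, and with equal totals 3482 were higher and 1014 lower. The median log2 fold change of the tested genes was 2.61 as deposited, -0.06 with quantile normalization and 1.58 with equal totals.

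The genes with the smallest p in the authors' deposited table were picked after their values were seen. On the captured side they were SEC23B (5.25 ± 0.157), RPL7L1 (6.67 ± 0.208), BZW1 (4.05 ± 0.127), TUBGCP6 (6.85 ± 0.235), CMTM6 (5.92 ± 0.205) and the transcription factor gene MYC (4.34 ± 0.151). On the control side they were SON (-6.56 ± 0.194), GATA3, KRT18 and the tubulin gene TUBA1B (-4.67 ± 0.193). The housekeeping genes GAPDH and ACTB were at -8.24 ± 0.385 and -10.91 ± 0.894 there.

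Sites for the seed were found in the 3' UTRs of some genes of both pathways. In the annotation of GRCh38, 7 of 28 TGF-β signalling components held CTCCAAG in the 3' UTR of their longest coding transcript, namely TGFBR1, TGFBR2, TGFBR3, TGFB3, SMAD2, SMAD7 and NEDD4L. In TGFBR3 the site was in the last of 17 exons, on the minus strand of chromosome 1 at 91680995 to 91681001, bases 2738 to 2744 of a 3' UTR of 3394 bases (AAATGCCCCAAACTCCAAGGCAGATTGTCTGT). TGFBR2 held 2 sites in exon 7, on the plus strand of chromosome 3 at 30692306 to 30692312 and at 30693209 to 30693215. SMAD7 held a site followed by A on the minus strand of chromosome 18 at 48920387 to 48920393, in exon 4. Of 27 genes of the CDK4/6 module, 5 held a site, and that of CDK6 lay 141 to 147 bases into its 3' UTR, on the minus strand of chromosome 7 at 92614993 to 92614999 (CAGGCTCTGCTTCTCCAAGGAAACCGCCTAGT). SMAD4, CDK4, CCND1 and RB1 held none. Over all 14708 protein-coding genes of the authors' deposited table with a 3' UTR, 1793 held a site. The numbers of the lists were not tested against that share, and 3' UTR length was not matched. The site of SMAD2, for example, began at base 27214 of a 3' UTR of 32870 bases.

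Genes with a seed site were compared with other genes. Of 2918 tested protein-coding genes with a 3' UTR, the 349 with a CTCCAAG site had a median log2 fold change of 2.41 and the 2569 without it one of 2.51. The difference of -0.10 ranked 125 from the highest among 420 sequences of 7 bases with the same composition (two-sided rank p of 0.595), which ran from -1.06 to 1.26. In a linear model with transcript length, 3' UTR length, GC content and mean expression, a site added 0.07 ± 0.103 (SE) to the log2 fold change. In the authors' deposited table, 1793 genes with a site had a median of -2.24 and 12915 without it one of -1.87, with a rank of 178 of 420 and a model coefficient of 0.30 ± 0.137, above 0 by more than 2 SE where the rank was not extreme. With an FPKM of at least 5 the coefficient was 0.345 ± 0.197. Genes are not independent replicates, so these ranks describe these libraries. Because FPKM rows were selected for a higher captured mean and captured FPKM was almost unrelated to the other table's mean count, these values can neither show nor exclude capture through seed sites.

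The tables were compared gene by gene, and genes are not independent replicates. Across 659 genes with a control mean of at least 1 FPKM and a log2 fold change below 0 in the authors' deposited table, called or not, control FPKM and that table's mean count had a Spearman correlation of 0.79. Across 2806 genes listed at 0 in control libraries and with a log2 fold change above 0 in the authors' deposited table, called or not, captured FPKM and the mean count had a correlation of 0.05. Within the FPKM table, captured libraries correlated with each other at 0.787 to 0.898 and control libraries at 0.857 to 0.866, and control with captured libraries at 0.182 to 0.215. Of 952 genes in both tables with a control mean of at least 1 FPKM and a higher captured mean, 476 were called lower in captured RNA in the authors' deposited table and 212 higher.

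**Figure D3:**
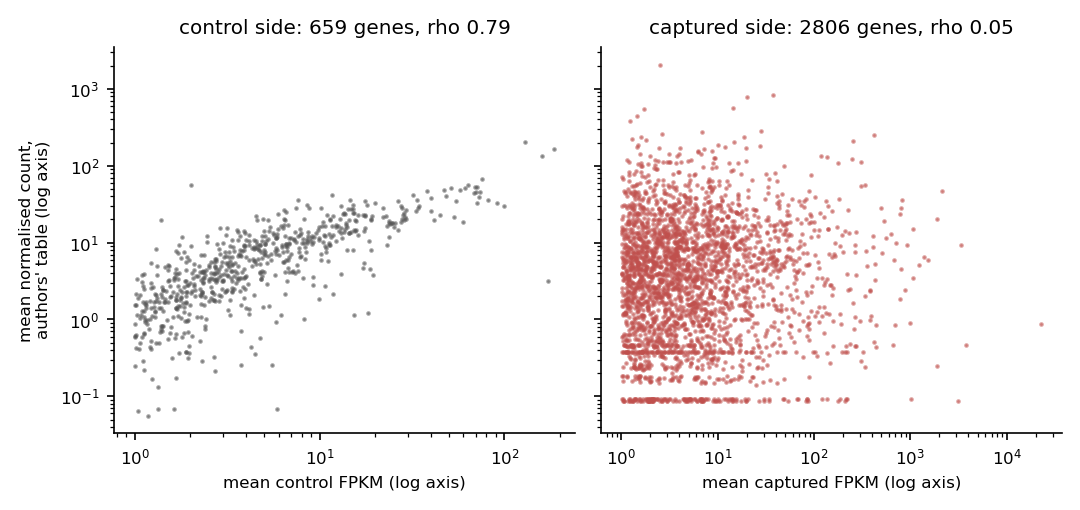
Mean normalised count of each gene in the authors' deposited table (y axis, log) against its mean FPKM (x axis, log), for 659 control-side genes against control FPKM (left) and 2806 captured-side genes against captured FPKM (right), 1 point per gene. Control FPKM and mean count rise together (Spearman 0.79), and captured FPKM and mean count have a correlation of 0.05.

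The shares of genes called differed between length classes, and no test was run on them. Classes also differ in gene type, as small RNA genes are short, and copies of near-identical sequence make their counts uncertain. In the FPKM table, 856 of 860 microRNA and 171 of 173 small nucleolar RNA genes were at 0 in every control library. Genes absent from control RNA can hardly be called lower, so these shares do not show an effect of length on capture. In the authors' deposited table, 870 of 1312 genes whose longest transcript is under 200 bases were higher and 4 lower, 66.3% and 0.305%. Of 6151 genes with transcripts of 4000 bases or more, 24.6% were higher and 47.9% lower. Among genes with a log2 fold change over 6, the median mean count was 9.07 for the 675 under 200 bases and 11.6 for the 510 of 4000 bases or more.

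**Figure D4:**
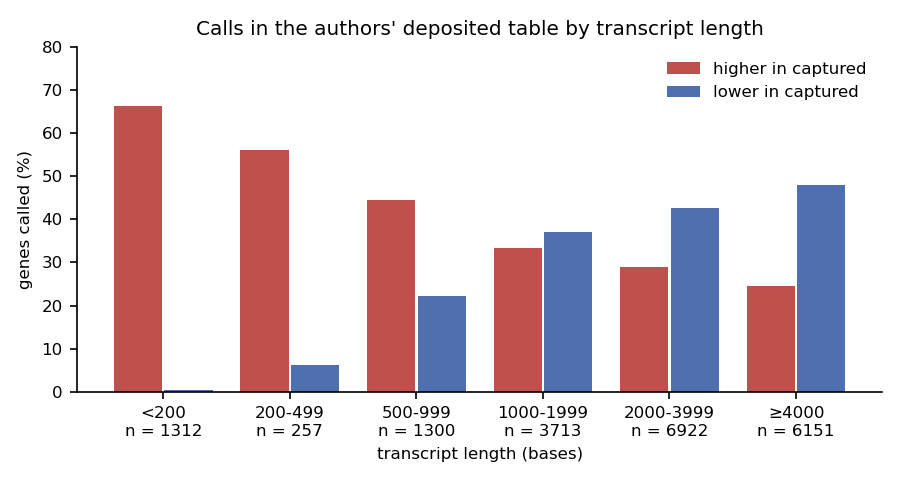
Percentage of genes (y axis) called higher (red) or lower (blue) in captured RNA in the authors' deposited table, by length of the gene's longest transcript in bases (x axis, with the number of genes in each class). The share called higher falls from 66.3% under 200 bases to 24.6% at 4000 bases or more, and the share called lower rises from 0.305% to 47.9%.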

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

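The following values were looked at after the data were seen. In the FPKM table, 56 synthetic spike-in sequences were at 0 in all 3 control libraries and above 0 in captured libraries, 50 of them in all 3, although the labels do not mention spike-ins and no comparison was planned for them. They stood out as values under spike-in names, outside the planned measurements, that were above their level in the control libraries. Their median captured FPKM of 5.53 was close to the 4.85 of all listed genes. As captured FPKM was almost unrelated to the other table's mean count among genes at 0 in control libraries, it is uncertain whether these values belong to spike-in sequences. ERCC-00157 was at 1404 FPKM in captured library 1 and at 0 in the other captured libraries, while ERCC-00016 was at 180, 183 and 61.8 FPKM in captured libraries 1 to 3. Of the 37 tested, limma called 37 higher, as it did every tested gene at 0 in all control libraries. These 37 remain among the 4511 genes called higher. Across the spike-in sequences, captured libraries 1 and 2 had a Spearman correlation of 0.838. No explanation specific to these sequences was tested.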

How the results depend on the processing

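Settings without the leading block, those with genes of both tables or the same genes, cameraPR, and the seed test on the authors' deposited table or on genes with control FPKM above 0 were chosen after the data were seen. By limma, 4511 genes were higher, 4 were lower and 2 lists were called, of which the CDK4/6 module is not read because of how genes were selected. Genes higher stayed within 1.5 times of this without trend (4506), without a filter (6010), with a pseudocount of 0.1 (4500), with at least 2-fold (4488) and in genes of both tables (3258), and 3 to 4 were lower there. Quantile normalization gave 1674 higher and 1760 lower, and equal totals 3482 higher, 1014 lower and 4 lists. An FPKM of at least 5 gave 1917 higher and 1 list, with 2123 genes tested. The authors' deposited table gave 7330 higher and 7978 lower, or 1873 and 537 of 3149 genes of the limma test. Without the leading block, 0 of 5050 genes were lower (0 also at an unadjusted p under 0.05) and 1 list was called. Genes of both tables gave 1 list, an estimated correlation 1 list and cameraPR, run on the authors' deposited table, 7 lists. Leaving out 1 library gave 4349 to 4824 genes higher and 4 to 9 lower, with 9 without captured replicate 1 and 9 without captured replicate 2, and 2 lists each time. The difference for seed sites lay between -0.442 and -0.049 in all settings, with rank p from 0.305 to 0.976, and the model coefficient between -0.11 and 0.345. The cause was not tested, except that the 4 genes lower by limma all belong to the leading block and that a stricter filter tests fewer genes.

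With the replicate number as a block, 4518 genes were higher and 7 lower, and no call changed among the 45 named genes tested. Same-numbered libraries did not deviate together (correlations of 0.000216, -0.00265 and 0.00437). Control libraries cannot deviate for the 3244 of 5062 tested genes that were at 0 in each of them. This check therefore cannot tell whether the numbers pair the libraries.

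Of 45 named genes tested, 27 changed sign under at least 1 setting. Quantile normalization and equal totals lower the listed genes as a group (median log2 fold change from 2.61 to -0.06 and 1.58), as the genes were selected for a higher captured mean. The amount differs between genes, and with equal totals a gene at 0 in every control library keeps that 0 and cannot turn. Turns under these scalings are therefore not evidence about single genes. With quantile normalization 23 did, as log2 fold changes ENG -0.10, SMAD4 -1.68, SMAD9 -0.84, INHBB -0.76, COL4A1 -0.083, PCNA -3.94, BCL2 -1.35, PDZK1 -1.76, XRN1 -1.32, AGO4 -2.45, DNAJB1 -3.55, TRIB3 -3.999, SCD -0.28, HIST1H1E -0.35, HIST1H4B -0.70, ZNF615 -0.82, ZNF197 -0.72, CD3D -0.32, KRT5 -0.49, TGFBR3 -1.23, TGFB1 -1.17, TGFB3 -1.61 and SMAD3 -1.72. With equal totals 19 did, SMAD7 -0.96, SMAD4 -2.74, INHBB -1.48, PMEPA1 -0.89, PCNA -4.89, BCL2 -1.69, PDZK1 -2.70, XRN1 -2.25, AGO4 -4.12, DNAJB1 -4.57, TRIB3 -5.14, SCD -1.16, HIST1H1E -1.20, ZNF615 -0.44, ZNF197 -1.26, TGFBR3 -1.24, TGFB1 -1.45, TGFB3 -2.54 and SMAD3 -2.82. In the authors' deposited table, 18 of the 34 with an adjusted p did, NRM -6.61, PEX2 -7.51, SMAD7 -6.19, SMAD4 -5.09, SMAD9 -2.21, INHBB -4.26, PMEPA1 -2.80, PCNA -8.27, PDZK1 -0.28, XRN1 -3.01, DNAJB1 -8.99, TRIB3 -2.03, SCD -4.95, HIST1H1E -5.65, TGFBR3 -1.19, TGFB1 -1.25, TGFB3 -3.79 and SMAD3 -0.21. Of these, SMAD9, INHBB, PDZK1, TGFBR3, TGFB3 and SMAD3 did not pass the adjusted threshold there, so their change of sign is uncertain. The same holds for PCNA, DNAJB1 and TRIB3, which limma did not call in the main setting (adjusted p of 0.234, 0.178 and 0.642). Without captured replicate 2, TRIB3 was at -0.12, and the values that left out 1 library ran from there to 0.51 (without captured replicate 3). With quantile normalization SMAD7 (0.06), PMEPA1 (0.04) and IFNB1, with equal totals ENG, SMAD9, CXCL10 and HIST1H4B, in the authors' deposited table PPT2-EGFL8 and ZNF615, and without control replicate 3 TGFB3 kept their sign and lost their call. Depth limits low genes, since a single fragment sets the smallest value above 0 that they can take, and the depth of control library 1 (estimated at about 947000 fragments) is itself uncertain.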

Other observations

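All tests of explanations here except the count of splits were chosen after the results they concern were seen, and the gene families were picked after their values were seen. Some gene families are given here beside all 21876 genes of the authors' deposited table, of which 7330 (33.5%) were higher and 7978 lower in captured RNA, and no enrichment was tested. Of 271 olfactory receptor genes, 194 were higher, 1 lower and 76 not called, with OR4D1 at a log2 fold change of 11.41 ± 1.83 (SE). Of 56 keratin-associated protein genes, found in hair, 37 were higher, as were 17 of 26 beta-defensin genes and 11 of 17 bitter taste receptor genes, with 0 lower by DESeq2 in each. Genes of small RNAs went the same way, with 724 of 1065 microRNA genes higher and 6 lower, and 153 of 252 small nucleolar RNA genes higher and 0 lower. Of 57 spike-in names in the same table, 32 were also higher and 0 lower. In the FPKM table, 226 of 232 olfactory receptor and 856 of 860 microRNA genes were at 0 in every control library. Of all 7035 genes there, 4898 were. A gene absent from control RNA can hardly be called lower. The few lower calls are therefore not a result about these families, and the share of 33.5% over all genes is not a like comparison. SNORD80 was at 9.54 ± 0.773 and MIR6834 at 14.91 ± 1.60. Whether these directions hold under other scalings could not be computed, since that table has no values per library, and copies of near-identical sequence make single members uncertain.

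Captured FPKM did not rise with the mean count over samples of the authors' deposited table, and a candidate explanation is that gene names are out of register with the values of the captured libraries in at least 1 table, as the 2 had a Spearman correlation of 0.04509 across 2806 genes at 0 in control libraries with a fold change above 0 in the authors' deposited table. Sampling noise in the FPKM table is argued against, since the lowest correlation between captured libraries was 0.7875. For the same 2806 genes, libraries outside the comparison counted in the mean are argued against as the main source. That table's own log2 fold change and mean count correlated at 0.9492 across them. The 634 genes with a log2 fold change of exactly 0 are not among them, so this value does not bear on those. Genomic DNA spread evenly over genes and counted under correct names is argued against, since transcript length and mean count correlated at -0.002842 across 2386 genes (-0.0018 with captured FPKM ranks removed), where the partial value on the control side was 0.594 across 620 genes, while genomic DNA spread unevenly stays open. That length test replaced a first one, the median count of genes of 4000 bases or more (11.6) over that of genes under 200 bases (9.07), because control-side medians did not rise with length either (13.9 at 4000 bases or more). The explanation was found in the same values it was tested on, which table would be affected stays open, lists abundant in control RNA would come out lower under it too, and no biological explanation was tested.

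The tables also gave opposite directions for genes present in control RNA, with 476 of 952 called lower and 212 higher in the authors' deposited table where FPKM was higher. A single scaling factor per library is argued against, since both log2 fold changes correlated at -0.04949 across 955 genes. An annotated gene on the other strand overlapped 61.3% of genes with opposite calls and 56.0% of those with the same call. The 95% upper bound of that excess was 13.67 percentage points, under the 20 set for it. As this counts annotated genes and not reads, and such reads could also raise genes called higher in both tables, it cannot exclude reads from the other strand. Names out of register may account for it, with a partial correlation of -0.04839 (95% interval -0.109 to 0.0138) once control ranks were removed, although any other error that unlinks captured values from genes would give the same value.

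The 6 libraries allow 10 splits into groups of 3, too few for a share under 0.05. The real split gave 4515 called genes by limma, the highest other split gave 0, and 1 split, the real one, gave as many. Apart from the leading block, FPKM rows had been kept only where the captured mean was higher, so they were selected on the real split. Of the 5062 tested genes, 3244 were at 0 in every control library and passed the filter only through captured values. The contrast of 4515 with 0 therefore cannot be read as evidence against chance.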
